A study of Oryza sativa with 4 samples.

How the data were processed

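Bulk RNA of protoplasts, which are plant cells freed of their walls by enzymes, was sequenced from root tips of 2 rice cultivars: 93-11, an indica cultivar, and Nipponbare, the japonica cultivar. Per the labels' protocols, seedlings were grown in nutrient solution for 3 days, tips of 5 mm were cut from 800 crown roots, poly(A) RNA was selected with oligo(dT) beads, and the libraries were sequenced on an Illumina instrument. Each cultivar has 2 libraries, and the run names in the labels place all 4 on one lane of one flow cell. Nothing in the labels says whether the 2 libraries of a cultivar came from separate protoplast preparations, so the p-values measure only the spread between these libraries, which may be technical.

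The submitters' processing notes name HISAT2 2.0.4 and HTSeq 0.11.2. The genome build, the annotation and the reason a gene is listed or left out are not given in the sources used here. The authors deposited 1 table per cultivar, named as RPM (reads scaled by the library total) for its 2 libraries. For 93-11 it lists 13486 genes and for Nipponbare 15657 genes, and 8576 identifiers are in both. Identifiers are of the LOC_Os kind except 116 in the 93-11 table and 36 in the Nipponbare table, which carry EVM names and of which none is shared.

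The deposited RPM values had lost their decimal points. Values below 1 RPM were intact, but between 61.6% and 76.5% of the values per library were written as up to 15 digits grouped in threes by dots, as when a dot is read as a mark between groups of digits. The smallest value of each library gave a whole library total: 21504426 and 21504715 reads for the 93-11 libraries, and 21504570 and 21504698 reads for the Nipponbare libraries. Every other value was a whole multiple of 1 read once a power of 10 was chosen, with 0 exceptions at a tolerance of 1e-06 of a read plus 1e-12 of the value. The power of 10 was set by taking the closest pair of candidates from the 2 libraries of a cultivar and, of equally close pairs, the lowest. The other library raised the value of 1 library for 964 genes in 93-11 and for 822 in Nipponbare. A gene was left out where the closest pair still differed by more than 0.4 in log10, which concerned 3 genes in 93-11 and 1 in Nipponbare. If both read numbers of a gene truly end in 0, the restored values are 10 times too low. In simulated tables damaged in the same way this befell 39 genes of 93-11, or 0.786 per 100 genes with 220 reads or more. For Nipponbare 42 simulated genes were restored wrongly, or 0.956 per 100 such genes, 41 of them 10 times too low. Values below 1 RPM had kept their decimal point and cannot be wrong in this way.

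The listed genes held 42.3% and 43.5% of the library totals in 93-11 and 55.6% and 55.7% in Nipponbare. RPM refers to the library total, genes outside the tables included. With 1 read worth 0.0465 RPM, a value of 0 reads allows up to 0.140 RPM, the worth of 3 reads in a library. A fold against a cultivar at 0 in both libraries was computed against that floor per library and is a lower bound. With 1 to 3 reads in the lower cultivar an exact binomial interval of 95% is given. These floors and intervals cover counting error only.

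The 2 cultivars were compared with limma 3.58.1 in R 4.3.3, with a trended variance, on log2(RPM + 1) for the 7269 shared genes with a mean of at least 1 RPM over the 4 libraries. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Differences are 93-11 minus Nipponbare on the log2(RPM + 1) scale, which understates the change of low genes. On simulated reads for this comparison, with 7280 genes past the filter, the test recovered 75.5% of the genes changed 1.5-fold, 93.5% of those changed 2-fold and 100% of those changed 4-fold or 8-fold. In that simulation 11 of 190 calls were false. It changed only a small part of the genes, equally often in each direction, and gave all libraries the same dispersion of 0.00133. The data differ in these settings, so the simulated rates need not hold for them.

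Gene lists were fixed before the data were examined, with identifiers written from knowledge of the rice literature. The tables do not pair identifiers with gene names, and the RefSeq gene table of the assembly ASM3414082v1 holds 0 identifiers of this kind. It served only as a check: of 130 distinct list genes, 99 had their symbol on the chromosome their identifier names, 28 symbols were not found and stayed unchecked, so their names rest on that knowledge alone (among them PLT1, PLT2, CRL1, PIN1d, FH1, AUX1, NR2, NADH-GOGAT1, NiR, NRT1.1A, HMA3, DRO1, KSL8, RSOsPR10, SNAC1, WRKY28, WRKY45 and WRKY53), and 3 that lay on another chromosome were dropped. The order of the 94 genes with a single hit followed the order of their identifiers (Spearman correlation 0.997 across genes). This was taken over all chromosomes together, and positions lay up to 4.57 megabases from the trend. It therefore cannot show that an identifier names the right gene. Of the remaining 127 genes in 13 lists, 49 are in both tables and 41 passed the filter. A further 12 lists defined by words in gene descriptions (among them histones, ribosomal proteins, heat shock proteins, photosynthesis and seed storage proteins) could not be formed, since no descriptions were at hand. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated.

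The genes named in the text follow a rule fixed at the same time: the 12 largest differences in each direction among called genes whose libraries do not overlap and which reach 10 RPM in the higher cultivar, up to 4 members of each list by p-value and those needed to say what did not pass, the most abundant genes, and all members of the list of genes known to differ between indica and japonica. Genes with no name at hand are given by identifier, at most 2 per direction. No coordinates are given, because the build is not given in the sources used here. The alternatives were 2 other pseudocounts, 2 other filters, 2 other scalings, a variance without trend, the replicate number as a block, each library left out in turn and, added after seeing the data, limma's voom on the restored reads.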

Results

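The data are the levels of rice genes in protoplasts of root tips from 93-11 (indica, 2 libraries) and Nipponbare (japonica, 2 libraries). The design holds a single comparison, which asks how gene levels differ between the cultivars. The library totals implied by the values lay within 289 reads of each other, from 21504426 to 21504715. Whether reads were subsampled to a common number is not given in the sources used here, so the totals may not be the sequenced depth. The listed genes held 42.3% and 43.5% of them in 93-11 and 55.6% and 55.7% in Nipponbare. Across the 8576 shared genes the 2 libraries of a cultivar had a Pearson correlation of log2(RPM + 1) of 0.997 in 93-11 and 0.998 in Nipponbare, while libraries of different cultivars had correlations of 0.452 to 0.457. These correlations are across genes, which are not independent replicates. The agreement within a cultivar is partly built in, because the restoration took the pair of candidates closest between its 2 libraries. Genes with at least 1000 reads over both libraries differed between them by a median of 5.12% in 93-11 and 2.58% in Nipponbare, and in both cultivars the libraries differed by more than counting noise (mean chi-square per gene 3.08 and 1.49).

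The libraries of the 2 cultivars differed in nearly every gene that could be compared. Cultivar and protoplast preparation cannot be told apart here. The calls are against the spread between the 2 libraries of a cultivar, which may be technical. Of 7269 genes tested, 4290 were higher in 93-11 and 2757 were higher in Nipponbare by limma at an adjusted p of 0.05. With a difference of at least 1 on the log2 scale, 3987 genes were higher in 93-11 and 2226 in Nipponbare, a share of 64.2% higher in 93-11, which was 53.3% after quantile normalization. The median difference of all tested genes was 1.44 on the log2 scale. It was 1.03 after median-ratio scaling, 0.49 after quantile normalization and 1.12 with no filter, so the lists are also described relative to it. A gene with 0 reads in 1 cultivar passes the filter only if its mean in the other is high enough. Small differences of such genes are therefore left out, as those of the list genes SHR1 (1.41 with no filter) and CRL1 (1.04). Quantile normalization moved 29 of the 41 tested list genes by over 1.5 times and median-ratio scaling 0. Median-ratio scaling still shifted abundant genes toward Nipponbare by nearly that much, as PIP1;1 from 1.47 to 0.93 and PBZ1 from -4.47 to -5.01. Single folds therefore depend on the scaling. Few genes were similar in RPM: 449 genes (6.18%) lay within 0.5 of equality, against 853 genes between -1.5 and -0.5 and 611 between 0.5 and 1.5. Equality here is a difference of 0 without further scaling. Within 0.5 of the median difference of 1.44 lay 1105 genes, so the count depends on the point taken as equal. The genes are those present in both tables, so these counts do not describe the whole transcriptome.

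**Figure D1:**
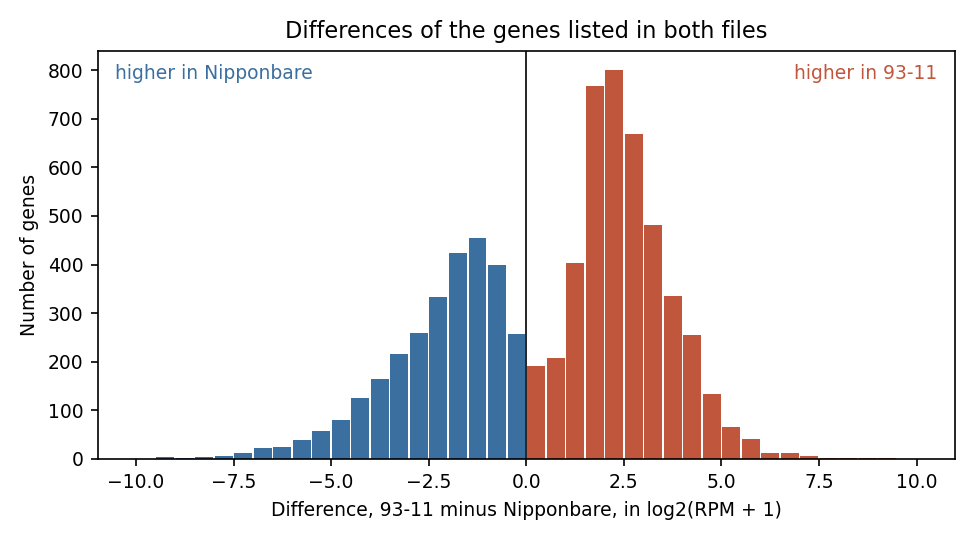
Number of genes (vertical axis) by the difference between the mean of the 2 93-11 libraries and the mean of the 2 Nipponbare libraries in log2(RPM + 1) (horizontal axis, bins of 0.5), for the 7269 tested genes. Red bars hold differences above 0 and blue bars those below 0, and there are 192 genes in the bin from 0 to 0.5, between peaks of 455 genes from -1.5 to -1 and 800 genes from 2 to 2.5. The filter on mean RPM leaves out small differences of genes with 0 reads in 1 cultivar, which affects this shape.

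Mitotic cyclin and B-type kinase genes were present in 93-11 and at or below 1.00 RPM in Nipponbare. All 8 tested members of the cell cycle list were higher in 93-11, both over all genes tested and adjusted over the list alone. Among the mitotic cyclins, CYCB2;2 (LOC_Os06g51110) was at 55.5 ± 0.953 RPM (SD, n = 2) in 93-11 and had 0 reads in both Nipponbare libraries, so it was at least 398-fold higher. CYCB2;1 (LOC_Os04g47580) was at 43.5 ± 2.27 RPM and also had 0 reads in Nipponbare, a difference of at least 312-fold. CYCB1;1 (LOC_Os01g59120) was at 78.3 ± 2.27 RPM in 93-11 and 1.00 ± 0.0329 RPM in Nipponbare, 78.3-fold higher. The plant-specific mitotic kinase CDKB2;1 (LOC_Os08g40170) was at 35.5 ± 1.18 RPM against 0.140 ± 0.132 RPM, and CDKB1;1 (LOC_Os01g67160) at 17.9 ± 1.41 RPM against 0.140 ± 0.0658 RPM. The A-type cyclins CYCA2;1 and CYCA3;1 had 0 reads in Nipponbare and 14.0 ± 0.460 and 4.72 ± 0.0986 RPM in 93-11. The smallest difference was that of PCNA (LOC_Os02g56130), the sliding clamp of DNA replication, at 16.8 ± 0.559 RPM against 2.70 RPM, 6.23-fold higher. The ninth member, the kinase CDKA1 (LOC_Os03g02680), which acts throughout the cycle, was listed for Nipponbare only, at 92.5 ± 3.09 RPM.

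The median fold of the 8 genes, with those at 0 set to their lower bound, was 114, and their median log2 difference of 4.53 lay 3.09 above the median of all genes. By limma's camera the list differed from other genes (adjusted p = 0.0107), and this call was lost with an adjusted p = 0.239 with an estimated correlation. All 8 calls held under median-ratio scaling and quantile normalization.

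Genes of the root meristem showed the same direction where both tables list them. The stem cell factor gene PLT1 (LOC_Os04g55970), which encodes a PLETHORA-type transcription factor, was at 117 ± 2.47 RPM in 93-11 and 0.209 ± 0.0329 RPM in Nipponbare, 560-fold higher with an unchecked identifier (limma log2 difference 6.61, SE 0.0676, adjusted p = 7.28e-07). It was the only one of the 4 shared members of the meristem list that passed the filter on low values. PLT2 (1.91 ± 0.0658 RPM), CRL1 (1.07 ± 0.329 RPM), which is needed for crown root initiation, and the quiescent centre gene QHB (0.512 ± 0.395 RPM) had reads in 93-11 and 0 reads in Nipponbare. With no filter PLT2 (adjusted p = 2.51e-05) and CRL1 (adjusted p = 0.00170) passed limma's test and QHB did not (adjusted p = 0.0507). Of the 7 auxin transporter genes in the list, only PIN2 (LOC_Os06g44970) was tested. It was 15.02-fold higher in 93-11, at 21.6 ± 0.0989 RPM against 1.44 ± 0.526 RPM. PIN1d did not pass the filter, with 0.767 ± 0.0329 RPM in 93-11 and 0 reads in Nipponbare. Another 4 were listed for Nipponbare only and could not be compared, namely PIN1b (5.12 ± 0.0657 RPM), AUX1 (3.88 ± 0.493 RPM), and PIN1a and PIN1c with 0 reads.

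The 5 tested markers of root hair, endodermis and stele were higher in 93-11 as well, except that PHO1;2 turned under quantile normalization. The stele gene SHR1 (1.65 ± 0.0329 RPM) and the endodermis gene SCR2 (1.40 ± 0.395 RPM) did not pass the filter and had 0 reads in Nipponbare, and other markers could not be compared. The root hair genes FH1 (LOC_Os01g67240), a formin, and EXPA17 (LOC_Os06g01920), an expansin, were at 42.0 ± 0.822 and 19.0 ± 0.756 RPM in 93-11. In Nipponbare FH1, whose identifier was not checked, had 1 read over both libraries, a ratio of 1805 with a counting interval of 324 to 71333, and EXPA17 was at 0.767 ± 0.0329 RPM, 24.8-fold lower. In the endodermis and exodermis list the silicon efflux transporter gene Lsi2 (LOC_Os03g01700) was at 11.5 ± 1.87 RPM in 93-11 with 0 reads in Nipponbare, a difference of at least 82.5-fold. In the stele list the secondary wall cellulose synthase gene CESA7 (LOC_Os10g32980) was at 14.7 ± 0.723 RPM in 93-11 against 0.163 ± 0.164 RPM in Nipponbare. Its fold of 90.3 rests on 7 reads in Nipponbare and was 52.7 without Nipponbare replicate 1 and 316 without Nipponbare replicate 2. The phosphate exporter gene PHO1;2 (LOC_Os02g56510) was 1.67-fold higher in 93-11 by limma (adjusted p = 0.00104), but its log2 difference of 0.63 became 0.17 with no call under median-ratio scaling and -0.35 under quantile normalization, where limma called it higher in Nipponbare (adjusted p = 0.0123). Listed for Nipponbare only were the secondary wall cellulose synthase genes CESA4 (6.32 ± 0.460 RPM) and CESA9 (2.72 ± 0.559 RPM), CSLD1 (5.28 ± 0.493 RPM), the auxin influx carrier gene AUX1 (3.88 ± 0.493 RPM) and the silicon channel gene Lsi1 (4.53 ± 0.493 RPM). RHL1, SCR1 and SUT1 were also listed for Nipponbare only, with 0 reads. Listed for 93-11 only were CASP1 (34.3 ± 0.0332 RPM) and the phosphate transporter gene PT2 (16.3 ± 0.296 RPM). These lists have 1 or 2 tested members each, all called in the same direction over all genes and adjusted over the list alone.

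**Figure D2:**
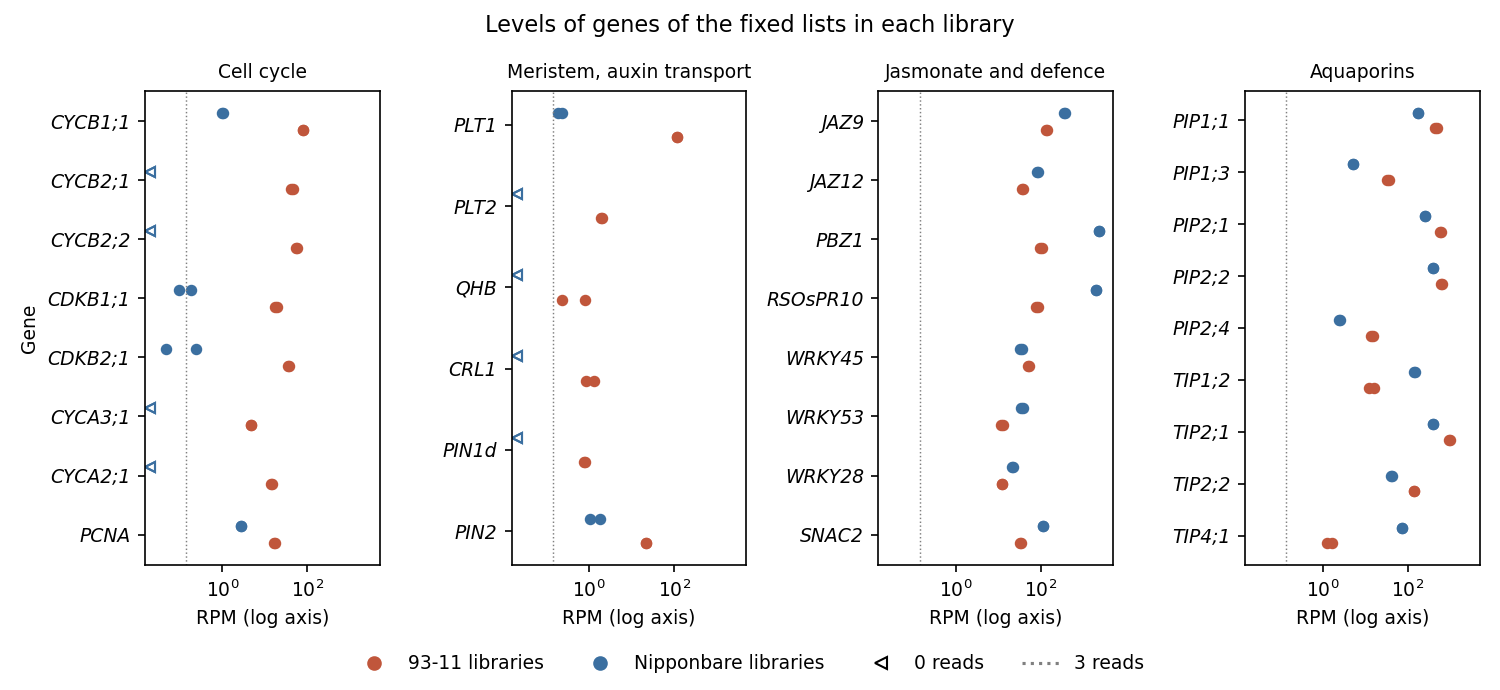
Levels in RPM (horizontal log axis) of the shared genes of 5 fixed lists (cell cycle, meristem, auxin transport, jasmonate and defence, aquaporins), with 1 symbol per library, red for 93-11 and blue for Nipponbare, open triangles for 0 reads and a dotted line at the worth of 3 reads (0.140 RPM). The cell cycle, meristem and auxin transport genes lie to the right in 93-11, whereas 7 of the 8 jasmonate and defence genes lie to the right in Nipponbare.

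Most tested defence genes were higher in Nipponbare, though the list's median lay within the wide range of random lists of similar mean RPM. The jasmonate, wounding and defence list has 19 members, of which 8 were tested, and 7 of these were higher in Nipponbare and 1 in 93-11, over all genes and adjusted over the list alone. The pathogenesis-related genes PBZ1 (LOC_Os12g36880) and RSOsPR10 (LOC_Os12g36830), both of the PR10 family, were at 2290 ± 3.66 and 1967 ± 35.2 RPM in Nipponbare, 22.4-fold and 24.1-fold above the 102 ± 6.74 and 81.6 ± 6.08 RPM of 93-11. As members of one family they may share reads, and the identifiers of RSOsPR10, WRKY45 and WRKY53 were not checked. SNAC2 (LOC_Os01g66120), a stress-responsive NAC transcription factor gene, was 3.36-fold higher in Nipponbare, and the defence regulator WRKY53 3.01-fold. The jasmonate repressor genes JAZ9 (LOC_Os03g08310) and JAZ12 were 2.66-fold and 2.22-fold higher, at 360 ± 6.74 and 83.0 ± 2.76 RPM in Nipponbare. WRKY45 (LOC_Os05g25770) went the other way, 1.49-fold higher in 93-11 by limma (adjusted p = 0.000369), but its log2 difference of 0.56 became 0.03 with no call under median-ratio scaling. JAZ11 (719 ± 1.87 RPM), listed for Nipponbare only, and the NAC gene SNAC1 (333 ± 16.9 RPM), listed for 93-11 only, have no counterpart to compare.

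The median log2 difference of this list was -1.46, which is 2.91 below the median of all genes. Camera called the list (adjusted p = 0.0107), and the call was lost with an adjusted p = 0.239 with an estimated correlation. Among 10000 random lists matched on mean RPM the median lay at percentile 22.3, and the median of such lists was -0.37. The middle 95% of them ran from -2.81 to 3.06, so only an extreme median would stand out. Because the mean RPM is over both cultivars, a large difference also changes which genes are matched. The comparison therefore does not settle whether the defence list is unusual. The median of the cell cycle list exceeded that of all 10000 lists matched to it.

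Aquaporins, the water channels of the plasma membrane (PIP) and the vacuole (TIP), split by member. Of 9 tested, 7 were higher in 93-11 and 2 in Nipponbare, over all genes, adjusted over the list alone, and under both other scalings. TIP2;1 (LOC_Os02g44080) was at 963 ± 23.2 RPM in 93-11 and 397 ± 1.35 RPM in Nipponbare, PIP2;1 (LOC_Os07g26690) at 596 ± 18.5 and 252 ± 2.27 RPM, and PIP1;3 at 34.1 ± 2.24 and 5.18 ± 0.0987 RPM, 6.58-fold higher in 93-11. In the opposite direction, TIP4;1 (LOC_Os05g14240) was 50.6-fold higher in Nipponbare, at 72.9 ± 0.0990 RPM against 1.44 ± 0.263 RPM, and TIP1;2 (LOC_Os01g74450) 10.3-fold higher, at 147 ± 4.47 RPM against 14.3 ± 2.40 RPM. The fold of TIP1;2 is close to the factor of 10 by which a restored value can be too low. The other members of the 14 could not be compared. TIP1;1 (1068 ± 105 RPM), PIP1;2 (203 ± 10.3 RPM), PIP2;3 (133 ± 6.64 RPM) and PIP2;6 (107 ± 5.19 RPM) were listed for 93-11 only, and PIP2;5, with 0 reads, for Nipponbare only. Camera did not call the list (adjusted p = 0.378), and its median log2 difference of 1.28 lay 0.17 below the median of all genes. It stayed below that median under median-ratio scaling (0.74 against 1.03) but lay above it under quantile normalization (1.89 against 0.49). Among 10000 random lists matched on mean RPM the list's median lay at percentile 77.4, and the median of such lists was -0.75. The middle 95% of them ran from -2.87 to 2.99.

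Genes of nitrogen nutrition differed by member. NR2 (LOC_Os02g53130), a nitrate reductase gene, was at 141 ± 4.57 RPM in Nipponbare and 0.372 RPM in 93-11 (16 reads over both libraries), 379-fold higher in Nipponbare with an unchecked identifier (limma log2 difference -6.69, SE 0.0644, adjusted p = 7.28e-07). The cytosolic glutamine synthetase gene GS1;1 (LOC_Os02g50240) was 2.05-fold higher in 93-11, at 601 ± 13.7 RPM against 293 ± 2.86 RPM, with a log2 difference of 1.03 that was 0.49 under median-ratio scaling and 1.92 under quantile normalization. NAR2.1 (LOC_Os02g38230), the partner protein of high-affinity nitrate transporters, was 1.87-fold higher in 93-11 (log2 difference 0.81). Under quantile normalization its direction turned (-0.08) and it was not called (limma adjusted p = 0.583). The nitrate reductase gene NIA1 (LOC_Os08g36480) did not pass (1.28 ± 0.0986 RPM in 93-11, 2.37 ± 0.986 RPM in Nipponbare, limma adjusted p = 0.0605), but was called higher in Nipponbare under both other scalings, with the replicate number as a block and without Nipponbare replicate 2. NAR2.1 lost its call without 93-11 replicate 2 (limma adjusted p = 0.0572). Over all genes 2 of the 4 tested members were higher in 93-11 and 1 in Nipponbare, and the counts adjusted over the list alone were identical. Their median log2 difference (0.14) and mean (-1.35) differed in sign. Of the members listed for 1 cultivar only, both for 93-11 were GS1;2 (98.9 ± 6.44 RPM) and the ammonium transporter gene AMT1;1 (24.0 ± 2.01 RPM). The 6 for Nipponbare included the glutamate synthase gene NADH-GOGAT1 (451 ± 6.54 RPM) and the nitrite reductase gene NiR (91.9 ± 2.27 RPM), with NRT1.1A, AMT1;3, NRT2.3 and NRT2.1 between 0.930 and 2.12 RPM.

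Among phosphate and potassium transporters, PT8 (LOC_Os10g30790), a high-affinity phosphate transporter gene, was 6.49-fold higher in Nipponbare, at 1794 ± 10.8 RPM against 276 ± 4.601 RPM, with a log2 difference of -2.69 that was -3.23 under median-ratio scaling and -1.77 under quantile normalization. HKT2;1 (LOC_Os06g48810) did not pass, with 1.56 ± 0.230 RPM in 93-11 and 1.79 ± 0.362 RPM in Nipponbare (limma adjusted p = 0.376), but was called higher in Nipponbare under both other scalings. With PHO1;2, given above, 1 of the 3 tested genes was higher in each cultivar. In the metal and silicon list both tested genes, Lsi2 and NRAMP1 (LOC_Os07g15460), were higher in 93-11. NRAMP1, a metal transporter gene, was at 2.91 ± 0.888 RPM in 93-11 with 0 reads in Nipponbare, at least 20.8-fold higher. In the list of phytoalexin synthesis, which forms antimicrobial diterpenoids, MAS (LOC_Os04g10010) was the only tested gene and was 13.9-fold higher in Nipponbare, at 7.44 ± 0.592 RPM against 0.535 ± 0.0329 RPM. CYP99A3 of that list went the other way, with 1.09 ± 0.0329 RPM in 93-11 and 0 reads in Nipponbare (limma adjusted p = 4.68e-05 with no filter). Listed for Nipponbare only were KSL8, at 29.9 ± 1.71 RPM, and CPS4 and KSL4, with 0 reads. The counts of these 3 lists were identical when adjusted over the list alone.

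Of 9 genes known to differ between indica and japonica cultivars, the tables allowed 2 to be compared, and both were called over all genes and adjusted over the list alone. NR2, above, was higher in Nipponbare, and DRO1 (LOC_Os09g26840, not checked), which controls the root growth angle, was 25.4-fold higher in 93-11, at 8.28 ± 0.197 RPM against 0.326 ± 0.132 RPM. HMA3, a vacuolar cadmium transporter gene, was listed for 93-11 only (0.488 ± 0.164 RPM) and TPP7, a trehalose-6-phosphate phosphatase gene, for Nipponbare only (7.74 ± 1.02 RPM). SD1, NRT1.1B, DEP1, GS3 and Wx were not analysed here.

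By the rule of size, the largest differences in favour of 93-11 were those of LOC_Os10g31660 (1143 ± 35.0 RPM against 0.930 RPM, log2 difference 9.21) and LOC_Os10g31530 (531 ± 7.72 RPM against 0 reads, log2 difference 9.06, at least 3807-fold). In favour of Nipponbare they were LOC_Os02g50710 (1153 ± 8.12 RPM against 0.744 ± 0.0658 RPM, log2 difference -9.37) and LOC_Os07g46860 (738 ± 11.97 RPM against 0.163 ± 0.0329 RPM, log2 difference -9.31). None of the 24 genes this rule chose belongs to a fixed list.

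Shared genes at 0 in 1 cultivar were mostly at 0 in Nipponbare, whose table lists 3775 and 3788 genes at 0 per library against 665 and 654 for 93-11. Of the shared genes, 1526 had a mean of at least 1 RPM in 93-11 and 0 reads in both Nipponbare libraries, whereas 76 showed the converse. The latter count was 122 without 93-11 replicate 2 and 181 with a limit of 0.1 RPM in place of 0 reads. Among genes listed for 1 cultivar only, 4193 of 7080 reached 1 RPM in Nipponbare and 3219 of 4907 in 93-11. The larger Nipponbare number goes with the longer list, since the median level was 1.84 RPM in Nipponbare and 3.09 RPM in 93-11. Of these genes, 1634 were at 0 in Nipponbare and 410 in 93-11. No test was applied to these counts. The 20 most abundant genes took 5.03% of the library total in 93-11 and 7.44% in Nipponbare, and 1 gene (LOC_Os02g44310) was in both sets, at 7583 ± 387 RPM and 3350 ± 22.8 RPM. Only 14 of the 20 genes of 93-11 and 15 of the 20 of Nipponbare are listed for both cultivars, so the rest could not be common. LOC_Os04g58110, rank 9 in 93-11 at 1880 RPM, was at 2046 RPM in Nipponbare, below the 2113 RPM of rank 20 there. The most abundant gene of Nipponbare was at 9502 ± 166 RPM there and 15.1 ± 0.822 RPM in 93-11. PBZ1 was the only member of a fixed list among these genes, at rank 17 in Nipponbare.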

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

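Signals were found outside the comparison between cultivars, in genes with EVM names, none of which is in both tables. The highest of them in 93-11 was EVM030192, at 305.93 RPM on average. The highest in Nipponbare was Add_EVM0009533, at 4673 ± 320 RPM (SD, n = 2), the fourth most abundant gene of that table. Both lie far above the 0.140 RPM that a count of 0 allows. No biological or technical explanation was tested for either.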

How the results depend on the processing

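The counts of genes called, of genes called with at least a 2-fold difference and of list genes called (7047, 6213 and 39) stayed within 1.5 times of these values under every alternative that was run. With the replicate number as a block they were 7070, 6214 and 40. With each library left out in turn, where the lone library of a cultivar is assumed to vary like the other cultivar, they ranged from 6530 to 7106, from 5882 to 6412 and from 37 to 42. Of the 7047 called genes, 6530 kept their call and direction under quantile normalization and 187 were called in the other direction. Under median-ratio scaling 25 were called in the other direction, and none was under the remaining alternatives. The directions that turned among the named genes were those of NAR2.1 (-0.077) and PHO1;2 (-0.35) under quantile normalization and of HKT2;1 without Nipponbare replicate 2 (0.010, and down to -0.25 with another library left out), and the cause was not tested. PHO1;2 and WRKY45 lost their calls under median-ratio scaling, and HKT2;1 became called under both scalings. NIA1 became called under 4 alternatives, namely both scalings, the block and without Nipponbare replicate 2. NAR2.1 lost its call under quantile normalization (limma adjusted p = 0.583) and without 93-11 replicate 2 (log2 difference 0.68). The set tests of the cell cycle and the defence list lost their calls only with an estimated correlation (adjusted p = 0.239 for both). Genes seen in 1 cultivar only numbered 1602, fell to 601 with a minimum of 5 RPM, because fewer genes reach it, were 1861 (1680 in 93-11, 181 in Nipponbare) with a limit of 0.1 RPM, and ranged from 1638 to 1663 with a library left out, where those seen in Nipponbare only, 76 with all 4 libraries, ranged from 75 to 122. Of the 50 most abundant genes 6 were common to both cultivars, against 1 of 20. Of those 50, 30 of 93-11 and 45 of Nipponbare are listed for both cultivars. The labels do not say that a replicate number marks a shared preparation. The deviations of same-numbered libraries had a correlation of 0.019 across genes, so no common shift was seen, which does not exclude shared handling. The 2 planned count tests were not run, because the unit of the tables is damaged RPM text from which reads had to be restored. Limma's voom on the restored reads, added after seeing the data, called 6967 genes.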

Other observations

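The tests of the cell cycle and of the gap near equality were chosen after their results had been seen, and the test on neighbouring genes was set before its correlation was computed but after the LOC_Os10g31 series had been noticed among the largest differences. Genes whose identifiers lie next to each other tended to differ alike. Across 2516 pairs of tested genes with adjacent identifiers no more than 20 apart in number, the correlation of the log2 differences was 0.218, above the highest of 10000 shuffles within chromosomes (0.081, permutation p = 0.0001, the smallest they can give). All 19 tested genes with identifiers beginning LOC_Os10g31 were called higher in 93-11, with a median log2 difference of 4.33, and 7 of the 12 largest differences in favour of 93-11 were among them, while without this series the correlation was 0.203 over 2503 pairs. No cause was tested, and reads shared between related neighbouring genes were not examined.

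Genes present in 1 table only numbered 4907 for 93-11 and 7080 for Nipponbare after unclear values were left out. Of these, 3219 reached 1 RPM in 93-11 and 4193 in Nipponbare, and 248 reached 100 RPM in 93-11 and 272 in Nipponbare. Genes without reads were not all left out of the tables, since 119 shared genes in 93-11 and 2020 in Nipponbare were listed with 0 reads in both libraries.

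Of the 8 cell cycle genes listed for both cultivars, 7 had means at or below 1.00 RPM in Nipponbare, with PCNA at 2.70 RPM and CDKA1, listed for Nipponbare only, at 92.5 RPM. Wrongly restored decimal points are unlikely to be the cause, because 6 of the 8 genes have both Nipponbare values intact in the table. Reads lost between a cultivar and the gene models are not excluded. The list's median lay at percentile 100 of 10000 random lists matched on mean RPM. Those lists draw genes one by one and do not show whether reads of a gene were lost. The list's camera call was also lost with an estimated correlation (adjusted p = 0.239). Fewer dividing cells as the only difference stay open: 7 of 7 shared markers of root hair, endodermis and stele were called higher in 93-11 or had 0 reads in Nipponbare only, against 60.6% of all shared genes with 10 reads or more (one-sided exact binomial p = 0.0302, with genes taken as independent), but PHO1;2 turned under quantile normalization (-0.35), and another 7 detected markers are listed for 1 cultivar, 5 of them for Nipponbare. A protoplast preparation that differed from the other and a difference between the cultivars cannot be told apart, because 0 of the 4 libraries hold both cultivars.

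Few genes had similar RPM in both cultivars, with 449 genes within 0.5 of equality, taken as a difference of 0 without further scaling. Within 0.5 of the median difference lay 1105 genes. The filter on mean RPM leaves out small differences of genes with 0 reads in 1 cultivar, and its part in the shortage was not tested. Wrongly restored decimal points could move genes by a factor of 10, but if last digits are independent between libraries, the shares of read numbers that end in 0 give an expected 0.901% of genes with 220 reads or more that end in 0 in both. The shares were taken after restoration, which lowers a gene whose read numbers both end in 0, so they cannot show such genes directly. Low counts as the whole cause would let the shortage disappear among abundant genes, yet 4.89% of 1391 genes with a mean of 50 RPM or more lay within 0.5 of 0 (exact binomial interval 3.82% to 6.16%), against 6.48% of the other genes, and 4.82% against 5.29% with a pseudocount of 0.1. Because that mean is over both cultivars, genes high in 1 cultivar only count as abundant and lower the share near 0. The comparison therefore cannot settle the part of low counts. The shape depends on the bands compared, since those 68 abundant genes stood against 227 between -1.5 and -0.5 and 61 between 0.5 and 1.5, but against 248 and 114 in bands of the same width centred on the tallest bins. A candidate explanation is that genes were listed because they changed in some other comparison, and this and a difference in biology cannot be told apart, because 0 genes left out of a table have values in both cultivars.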
